A study of Mus musculus with 12 samples.

How the data were processed

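Expression was measured in bone marrow-derived macrophages on 12 Affymetrix Mouse Gene 2.1 ST arrays, which probe each transcript along its length. Per the labels' protocols, total RNA was amplified, labelled with biotin and hybridized to array strips. Per the submitters' processing notes, the arrays were processed with Affymetrix Expression Console and RMA, a procedure that corrects background, applies quantile normalization and summarizes the probes of each row. The versions of these tools and the settings of that step are not given in the sources used here. The deposited values are log2 values with up to 2 decimals, between 2.15 and 12.85, with medians per array between 4.49 and 4.57. Because RMA brings all arrays to nearly the same distribution, a change in the total RNA of a cell is not visible in these values. Differences of dim rows are compressed, since background is a large part of their signal. Array scanner files, the strip and the date of each array were not used here, so a batch that followed the groups could not be told apart from them.

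The value table held 34472 rows. The platform table paired 23521 of them with 1 gene symbol, 1814 with several and 9137 with none, and no gene was named from the latter 2 kinds. Of the rows with 1 symbol, 23328 were matched by Entrez number to a RefSeq gene table, which changed 0 symbols. For 1082 symbols with more than 1 row, the row with the highest mean over all 12 arrays was used, without regard to group. A gene was tested if its value exceeded the 40th percentile of the rows with 1 symbol, which lay between 4.31 and 4.35, on at least 3 arrays. This left 14079 genes and removed 8101.

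Group and replicate number were taken from the sample titles: wild type or knockout, saline or R848, with 3 arrays in each of the 4 groups. All 12 arrays entered 1 linear model per gene (limma 3.58.1 in R 4.3.3, lmFit and eBayes) with a mean per group and no covariate. The contrasts were R848 against saline within each genotype, knockout against wild type within each treatment, the difference between the R848 responses (interaction), and each factor averaged over the other. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05, and every adjusted p given for a gene is limma's. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision. Replicate numbers were checked for pairing by the correlation of residuals, with a minimum of 0.1 for every pair of the groups compared. The knockout saline and knockout R848 arrays met it, with 0.27, 0.17 and 0.28 for numbers 1, 2 and 3, a pairing that comes from the data and not from the labels.

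Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01, and adjusted over the lists within each contrast. The same test with an estimated correlation, and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were alternatives. The gene lists, the contrasts, the filter, a window of 50 tested genes on either side of Rasgef1b for a two-sided Fisher's exact test of genotype differences, and the rule for naming genes were fixed before the data were examined. That rule takes the 10 largest increases and the 10 largest decreases per contrast among genes past the threshold whose groups do not overlap, without gene-model or clone names. For the interaction no overlap rule was used, and where fewer than 5 genes passed in a direction, the genes with the smallest p up to 5 were added. For genotype averaged over treatments it takes the 5 largest in each direction, and for each gene list up to 4 members with the largest change, those past the threshold first. Rasgef1b is always named.

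Alternatives covered an intensity trend with robust spread, no filter and a stricter filter on dim rows, median centring and cyclic loess between arrays, fitting only the arrays compared, array weights, the replicate number as a block, arrays of 1 genotype and number as correlated pairs (limma's duplicateCorrelation), 1 surrogate variable, a minimum log2 change of 1, all rows of a gene, and leaving out each array in turn. The fit was tested on simulated data with the mean of each of the 14079 genes, equal in all groups, and the spread that limma estimated. In these data 200 genes changed in the R848-treated knockout group. The noise was independent between arrays, without correlation of same-numbered arrays. Its spread was limma's moderated estimate, which varies less between genes than unmoderated estimates. For both reasons recovery may be lower in the real data, and each size of change was drawn once. For knockout against wild type with R848, 83% of the genes changed by 0.5 on the log2 scale were recovered, and 99.5% of those changed by 1. For the interaction these shares were 23.5% and 98.5%. Unchanged genes called were 5 and 13 for knockout against wild type with R848, and 0 and 11 for the interaction.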

Results

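Macrophages grown from mouse bone marrow in medium conditioned by L929 cells were compared between wild-type mice and mice in which a floxed Rasgef1b gene is removed by a Vav-driven Cre recombinase, active in blood-forming cells. Rasgef1b encodes a guanine nucleotide exchange factor for Ras-family GTPases. Cells of each genotype received saline, or R848, a small agonist of the endosomal receptors TLR7 and TLR8, for 4 h. The labels give no time for saline. They name no group with Cre alone, so an effect of Cre cannot be told apart from loss of Rasgef1b. RNA of 3 replicates per group was hybridized to whole-transcript arrays, and values are RMA log2 intensities, so a difference of 1 is a doubling. Over the tested genes, arrays of the same group correlated between 0.9909 and 0.9964, and arrays of different groups between 0.9159 and 0.9945. The first principal component held 83.7% of the variance and separated R848 from saline, the second held 3.8% and separated the genotypes, and the third held 3% and set replicate number 1 of each group apart from number 3.

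Rasgef1b, on chromosome 5, was read by 1 row. It stood at 9.12 ± 0.08 (SD, n = 3) in wild-type cells with saline and 9.79 ± 0.09 (n = 3) with R848, and at 8.41 ± 0.46 (n = 3) and 9.14 ± 0.47 (n = 3) in knockout cells. In each treatment all 3 knockout arrays lay below all 3 wild-type arrays, which gives a two-sided exact permutation p of 0.1, the smallest that 3 against 3 arrays allow. The knockout difference was -0.71 with saline (limma adjusted p = 0.158) and -0.65 with R848 (adjusted p = 0.333), neither past the threshold. Averaged over treatments it was -0.68 ± 0.15 (SE, adjusted p = 0.036). Knockout replicate 2 was lowest in both treatments, at 7.88 and 8.60, and without it the differences were -0.445 and -0.385. Signal remained in the knockout, and which exon is deleted and which probes lie outside it are not given in the sources used here, so this row checks the labels only in part. R848 raised Rasgef1b by 0.67 ± 0.21 (SE, adjusted p = 0.0212) in wild type and by 0.73 ± 0.21 (adjusted p = 0.0125) in knockout. The averaged call ended with an intensity trend and robust spread (adjusted p = 0.0643), and with arrays of 1 genotype and number fitted as correlated pairs (0.054), while other alternatives with all arrays gave 0.0189 to 0.048. It also ended without any of the 6 wild-type arrays (adjusted p between 0.0502 and 0.098) and without knockout replicate 2 of either treatment (-0.55 each, adjusted p = 0.0632 with saline and 0.0655 with R848).

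**Figure D1:**
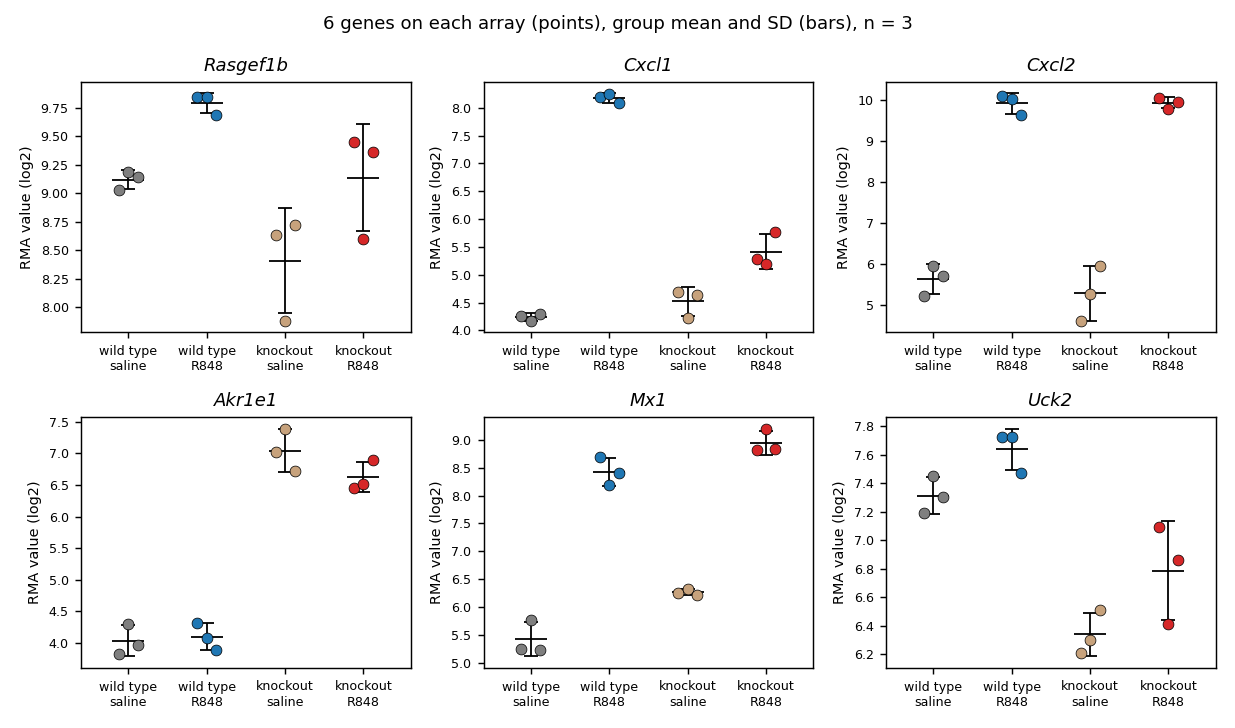
RMA values (log2, vertical axes) of 6 genes on each of the 12 arrays (points) by genotype and treatment, with the group mean and SD (bars, n = 3). The axes do not start at 0. Rasgef1b lay lower in both knockout groups, Cxcl1 reached 8.17 in R848-treated wild-type cells against 5.42 in knockout cells, and Akr1e1 had means of 4.03 in wild-type and 7.04 in knockout cells with saline.

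The response of wild-type macrophages to R848 was led by inflammatory mediators. The largest increases were in Il1b, the precursor of interleukin 1 beta, which went from 4.08 ± 0.05 to 12.11 ± 0.02 (SD, n = 3), and Ptgs2, the inducible cyclooxygenase, which rose by 8.03 ± 0.09 (SE). Acod1, which makes itaconate, rose by 6.91, the vasoconstrictor peptide Edn1 by 6.23, Il1a by 6.17 and the acute-phase gene Saa3 by 5.86. The neutrophil chemoattractant Cxcl3 rose from 3.87 to 9.87. The lymphocyte activation marker Cd69 rose by 5.57 and the receptors Gpr84 and Fpr2 by 5.54 and 5.53. Largest among the decreases was Rasgrp3, a Ras activator, which fell from 8.38 ± 0.12 to 4.68 ± 0.21 (SD, n = 3). Then came Zfp36l2 (-3.50), the ERK phosphatase Dusp6 (-3.34), Rgs2 (-3.27), Snx30 (-3.15), Arhgap25 (-3.04), Snx24 (-3.03), Arrdc3 (-2.96), the Ras GTPase-activating protein Rasa3 (-2.92) and the chemokine receptor Cxcr4 (-2.86).

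Of the gene lists, inflammatory cytokines and mediators moved most in wild type: 23 of 24 tested members rose, with a median of 3.02 (camera adjusted p = 6.06e-27). Among chemokines 19 of 23 rose and 1 fell, with Cxcl3, Cxcl10 (4.62), Ccl5 (4.43) and Cxcl2 (4.30) largest. Of the NF-kB subunits and feedback inhibitors, 25 of 29 rose, among them Socs3 (4.64), Nfkbiz (4.25), Tnfaip3 (3.74) and Ier3 (3.44). Antigen presentation and co-stimulation had 17 of 25 members higher and 0 lower, led by Cd40 (4.34), Icam1 (3.25) and Cd274 (3.04). In the glycolysis and hypoxia list 10 of 22 rose, led by Pfkfb3 (3.21) and Adm (2.01), and 3 fell. These 5 lists also passed camera with an estimated correlation. Interferon-stimulated genes had 26 of 32 higher, with Gbp5 (5.28), Mx1 (3.01) and Usp18 (2.73), but adjusted p = 0.0955 with an estimated correlation. TLR receptors and adaptors had 15 of 27 higher, led by Tlr2 (3.12), and 6 lower (adjusted p = 0.0767 with an estimated correlation). Cell cycle genes had 26 of 31 lower and 0 higher, with the licensing factor Cdc6 at -1.71 and the helicase subunits Mcm4 at -1.59 and Mcm6 at -1.56 (adjusted p = 3.86e-08, and 0.449 with an estimated correlation).

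Regulators of small GTPases went both ways in wild type. Of 34 tested Ras and Rap GTPases, exchange factors and GTPase-activating proteins, 15 rose, with Rapgef2 (2.99) and Ralgds (2.44), and 8 fell, with Rasgrp3 and Rasa3 (camera adjusted p = 0.0355, and 0.468 with an estimated correlation). Ras-ERK output genes had 4 of 17 higher and 10 lower, Dusp6, Ccnd1 (-1.98) and Etv5 (-1.71) lowest (camera adjusted p = 0.0623, not past the threshold). A second row of Etv5, with a mean of 4.65, changed by -0.05, while a second row of Socs3, with a mean of 5.525, rose by 2.58. Proteases, serpins and coagulation genes had 13 of 25 higher, led by Mmp14 (4.56), Serpinb2 (4.41) and Adamts4 (3.71), and 7 lower (camera adjusted p = 0.00654, and 0.383 with an estimated correlation). Cholesterol synthesis had 6 of 17 higher and 1 lower (0.0359, and an adjusted p of 0.626 with an estimated correlation). Heat shock and unfolded protein genes had 7 of 20 higher, led by Hspa1b (3.00), and 4 lower (0.0412, and an adjusted p of 0.12 with an estimated correlation). Macrophage identity genes did not pass as a list (camera adjusted p = 0.996), though Cebpb rose (2.25) and Mertk fell (-1.79). Nor did immediate early transcription factors, with 10 of 21 higher and 7 lower (camera adjusted p = 0.224), NRF2 genes, with 6 of 16 higher, led by Slc7a11 (4.09), and 5 lower (0.0904), or housekeeping genes, with 0 of 13 higher and 4 lower (0.367). For cholesterol efflux 2 of 10 rose and 3 fell (0.462). Alternative activation (4 of 15 higher and 4 lower, 0.726) and adhesion genes (10 of 28 higher and 9 lower, 0.36) had negative medians and positive means. No marker list of another cell type passed, the smallest camera adjusted p being 0.195.

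In all, 5387 of 14079 genes passed the threshold in wild type, 2062 higher and 3325 lower, and 1014 also changed at least 2-fold, 538 higher and 476 lower. For 6776 genes the groups did not overlap, where chance gives 10% of genes. The share of higher genes depended on the scaling: it was 38.3%, against 62.2% after median centring of the arrays and 48.5% after cyclic loess. Centring also moved the median change of all genes from -0.02 to 0.11. Of the 538 genes raised at least 2-fold, 44 (8.2%) lay under the dim limit with saline, Il1b and Ptgs2 among them. Their fold changes may be understated, which was not measured.

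In knockout macrophages, R848 raised inflammatory mediators as well. Il1b rose by 8.05, Ptgs2 by 7.95, Acod1 by 6.90, Cxcl3 by 6.16, Saa3 by 6.11, Edn1 by 6.07, Il1a by 5.94, Gpr84 by 5.65 and Fpr2 by 5.48, and Cd69 reached 10.10. The largest decreases were again in Rasgrp3 (-3.96), Zfp36l2 (-3.68), Dusp6 (-3.57), Arrdc3 (-3.38), Cxcr4 (-3.31), Rgs2 (-3.29), Snx30 (-3.25) and Snx24 (-3.16), followed by Irf2bp2 (-3.06) and Lyl1 (-3.05). Arhgap25 and Rasa3, named for wild type, are outside these 10, with -3.00 and -2.87. A second row of Irf2bp2, with a mean of 6.27, changed by -0.53. Cytokines and mediators had 23 of 24 members higher, chemokines 20 of 23, NF-kB subunits and inhibitors 24 of 29 and interferon-stimulated genes 25 of 32 (adjusted p = 0.0975 with an estimated correlation). Cell cycle genes had 27 of 31 lower (adjusted p = 0.449 with an estimated correlation). Antigen presentation had 15 of 25 higher and 1 lower, glycolysis 10 of 22 higher and 3 lower, and TLR receptors and adaptors 15 of 27 higher and 5 lower, which camera no longer called with an estimated correlation (adjusted p = 0.0561, 0.0533 and 0.0975). The same held for cholesterol synthesis, with 7 of 17 higher and 1 lower, and proteases and serpins, with 13 of 25 higher and 7 lower (adjusted p = 0.599 and 0.441 with an estimated correlation). The threshold was passed by 5858 genes, 2193 higher and 3665 lower, with 1086 at least 2-fold. The share of higher genes was 37.4%, 63.6% after median centring, which moved the median of all genes to 0.12, and 49.4% after cyclic loess. Averaged over genotypes, R848 changed 7039 genes, 2720 higher (38.6%, against 66.7% after median centring and 50.4% after cyclic loess) and 4319 lower, and 1043 at least 2-fold.

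Whether the knockout changes the response to R848 is the question of the interaction. The R848 responses of the 2 genotypes correlated with a Pearson r of 0.9681 and a Spearman rho of 0.8769 across genes, which are not independent replicates. Of the genes past the threshold, 1740 were higher in both genotypes, where independent lists would share 321, and 2955 were lower in both, against 866. These lists share 1 estimate of the spread per gene, so they are not fully independent. The interaction, which tests the difference between the responses, was past the threshold for 2 genes of 14079, with 694 at an unadjusted p under 0.05. These 694 are no more than the share of 0.05 of the tested genes that chance gives. Cxcl1, a chemokine that draws neutrophils, rose from 4.24 ± 0.07 to 8.17 ± 0.09 (SD, n = 3) in wild type and from 4.52 ± 0.25 to 5.42 ± 0.31 (n = 3) in knockout. Its interaction was -3.03 ± 0.20 (SE, limma adjusted p = 4.58e-06). Its saline values in wild type lay under the dim limit, and it lies 36 tested genes from Rasgef1b on chromosome 5. The neighbouring genes Cxcl2 and Cxcl3 had interactions of 0.37 and 0.15 and reached 9.94 and 9.90 in knockout cells with R848. Enpp4, an ectonucleotidase family member, had an interaction of 0.91 ± 0.12 (SE, adjusted p = 0.0226), from 4.73 to 4.94 in wild type and from 4.46 to 5.59 in knockout. The Enpp4 call was lost without any of the 9 arrays outside the knockout saline group, with adjusted p between 0.0545 and 0.122, while that of Cxcl1 held in all 12 cases.

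Further genes with the smallest interaction p did not pass. On the higher side these were Dusp5 (0.77, limma adjusted p = 0.409), Gpr18 (0.57), Mybl2 (0.51) and Cytip (0.61). A second row of Mybl2, with a mean of 4.48, had an interaction of 0.01. On the lower side were Csf3, the granulocyte growth factor (-0.91, adjusted p = 0.127), Rps15a-ps5 (-0.50), the interleukin 1 family gene Il1f9 (-1.02, adjusted p = 0.277) and Acad12 (-0.48). Among the lists, Ras-ERK output genes had a positive median interaction of 0.23 (camera adjusted p = 0.00311), which did not hold with an estimated correlation (adjusted p = 0.635), and 0 of 17 members passed. Genes raised by R848 had a median interaction of 0.03 and genes lowered by it one of -0.04, each compared with the other genes (camera p = 0.00609 and 0.00213, with an estimated correlation p = 0.0475 and 0.222, and against no change, by fry, p = 0.163 and 0.311). The 0.03 became 0.01, no longer past the threshold of camera, without wild-type saline replicate 3, 0.0167 without wild-type saline replicate 2 and 0.015 without wild-type R848 replicate 3. The -0.04 became -0.0133, no longer past it, without wild-type saline replicate 1 and -0.0233 without knockout R848 replicate 2.

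**Figure D2:**
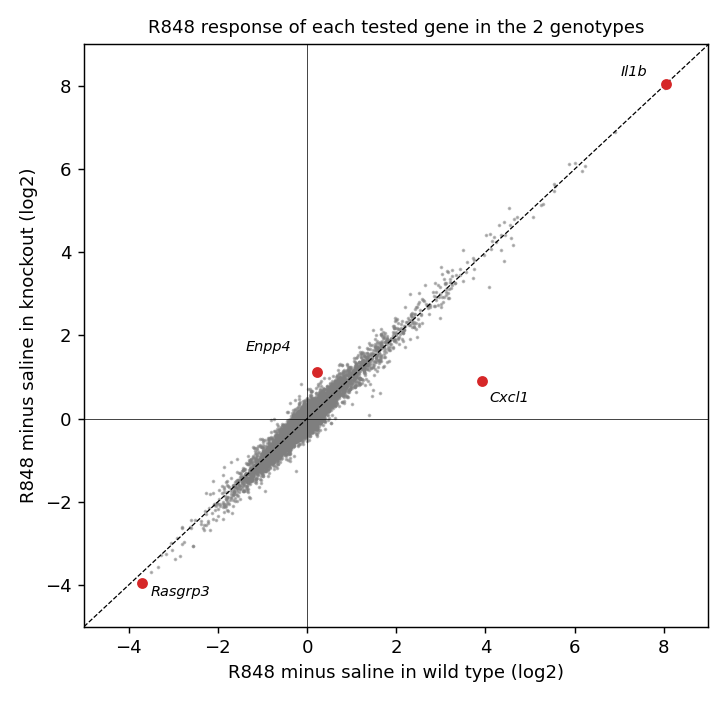
Change with R848 (log2) of each of the 14079 tested genes in wild type (horizontal axis) and in knockout (vertical axis), with the line of equal change dashed. Cxcl1, at 3.93 and 0.90, lies far below the line.

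Without R848, the genotypes differed at few genes. The largest increases in knockout cells were in Akr1e1, an aldo-keto reductase, from 4.03 ± 0.25 to 7.04 ± 0.34 (SD, n = 3), Erdr1 (1.99 ± 0.13, SE), Kcnma1, named for a potassium channel (1.91 ± 0.26), Mid1, a ubiquitin ligase (1.52 ± 0.22), and Gdf3, a TGF-beta family ligand (1.25 ± 0.11). The class I histocompatibility gene H2-Q5 (0.90), the interferon-stimulated genes Mx1 (0.85), Ifit1 (0.67) and Stat2 (0.62), and Hpse, which encodes heparanase (0.80), were also higher. Uck2, a uridine-cytidine kinase, was lower by -0.97 ± 0.14 (SE), followed by Wwc2 (-0.72), Hells (-0.71), the nucleolar protein gene Nop58 (-0.65), Mybl2 (-0.63), the glucose transporter gene Slc2a1 (-0.57), Jag1 (-0.57), Bzw2 (-0.57), Snrpa1 (-0.55) and Adss (-0.55). Wild-type Akr1e1 lay under the dim limit, so its difference may be understated. A second row of Kcnma1 lay at 3.89 and differed by 0.05, while the second row of Erdr1 differed by 1.80. Second rows with means above the dim limit differed less than the rows used for H2-Q5 (0.27), Mid1 (0.67), Mybl2 (-0.09) and Slc2a1 (-0.20).

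By list, interferon-stimulated genes were higher in saline knockout cells with a median of 0.30 (camera adjusted p = 1.04e-19, and 0.0957 with an estimated correlation). 4 of 32 passed over all genes and 18 adjusted over the list alone. Markers of dendritic cells also had a higher median, 0.16 (camera adjusted p = 0.000779, and 0.0688 with an estimated correlation), with 0 of 9 past the threshold and Cd209a at 0.52 (adjusted p = 0.0716). Antigen presentation genes had a median of 0.13, with 0 of 25 past the threshold and 7 adjusted over the list alone (camera adjusted p = 2.27e-06, and 0.0957 with an estimated correlation). Glycolysis and hypoxia genes were lower with a median of -0.22, which held with an estimated correlation (adjusted p = 0.00893). 2 of 22 passed, Slc2a1 and Pgk1 (-0.44), and 10 adjusted over the list alone. Cholesterol synthesis (median -0.28), cell cycle (-0.14), Ras-ERK output (-0.15) and NRF2 genes (-0.11) were lower, and TLR receptors and adaptors (0.09) and macrophage identity genes (0.10) higher by camera. None of these 6 held with an estimated correlation, with adjusted p between 0.129 and 0.696, and 0 of their members passed. The mean of the cholesterol synthesis list was 6.90 on knockout replicate 3, 7.32 and 7.43 on knockout replicates 1 and 2, and 7.45 to 7.61 in wild type. For cell cycle genes, knockout replicate 2 was lowest at 7.03, with 7.30 and 7.52 on the other knockout arrays and 7.13 to 7.69 in wild type.

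The saline genotype difference was past the threshold for 47 genes, 20 higher and 27 lower, and for 5 of them at least 2-fold. There were 1767 genes at an unadjusted p under 0.05, where chance gives a share of 0.05 of the tested genes. For 2263 the groups did not overlap, where chance gives 10%. The count of 47 was 10, 20 and 28 without wild-type saline replicate 3, 1 and 2, 13 without knockout saline replicate 2, 29, 26 and 25 without wild-type R848 replicate 1, 2 and 3, and 8 in a fit of the 6 arrays compared. The share of higher genes, 42.6%, was 61.8% after median centring and 57.4% after cyclic loess.

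With R848, the largest decrease in knockout cells was in Cxcl1, lower by -2.76 ± 0.14 (SE, limma adjusted p = 1.5e-07). The interferon-inducible gene Ifi208 was lower (-1.91), with Il1f9 (-1.04), the cystine transporter gene Slc7a11 (-0.98), Ints6l (-0.92), Uck2 (-0.85), Serpinb2, an inhibitor of plasminogen activators (-0.78), Csf3 (-0.73), Dkc1, which encodes the pseudouridine synthase dyskerin (-0.68), and Wwc2 (-0.66). A second row of Ints6l, with a mean of 4.42, differed by -0.06. Higher were Akr1e1 (2.53 ± 0.17, SE, possibly understated because wild type lay under the dim limit), Kcnma1 (1.98), Erdr1 (1.87), Mid1 (1.84), Gdf3 (0.94), Enpp4 (0.65), Phf11b (0.56) and Gpr18 (0.46). These 8 were all the genes higher past the threshold, and 11 were lower, for a total of 19. There were 1230 genes at an unadjusted p under 0.05, where chance gives a share of 0.05 of the tested genes. Of 20 higher with saline and 8 higher with R848, 5 were shared (Akr1e1, Erdr1, Gdf3, Kcnma1 and Mid1), where independent lists would share 0.0114. Of the lower genes, 2 were shared, Uck2 and Wwc2, against 0.0211. The 2 comparisons share 1 estimate of the spread per gene, and same-numbered knockout arrays had correlated residuals, so the lists are not independent. Erdr1 and Mid1 both lie on the X chromosome and may not be separate differences. The share of higher genes was 42.1%, 59.3% after median centring and 57.7% after cyclic loess.

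Interferon-stimulated genes were again higher in R848-treated knockout cells, with a median of 0.33 (camera adjusted p = 8.65e-29, and 0.0481 with an estimated correlation). 0 of 32 passed over all genes and 23 adjusted over the list alone, and the largest differences were in Tnfsf10 (0.65, limma adjusted p = 0.0863), Oasl1 (0.63) and Ifit2 (0.57). Beside them, dendritic cell markers had a median of 0.09 (adjusted p = 0.0319, and 0.141 with an estimated correlation), with Cd209a at -0.03. Antigen presentation genes were higher with a median of 0.11 and glycolysis genes lower with one of -0.15, both holding with an estimated correlation (adjusted p = 0.0466 and 0.00899). 0 of 25 and 0 of 22 members passed over all genes, and 5 and 6 adjusted over the list alone. Cell cycle (median -0.32), cholesterol synthesis (-0.25), NRF2 (-0.15) and protease and serpin genes (-0.05) were lower, and cytokines (0.13) and TLR receptors and adaptors (0.06) higher, by camera with the preset correlation only. Their adjusted p with an estimated correlation lay between 0.0777 and 0.581. Of their members, Slc7a11, Serpinb2 and Csf3 passed, and Csf3, a cytokine, was lower although its list's median was higher. The mean of the cholesterol synthesis list was 7.26 on knockout replicate 3. It was 7.75 and 7.80 on knockout replicates 1 and 2, against 7.79 to 7.91 in wild type. For cell cycle genes, knockout replicate 2 was lowest at 6.12, with 6.41 and 6.47 on the other knockout arrays and 6.43 to 6.71 in wild type.

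**Figure D3:**
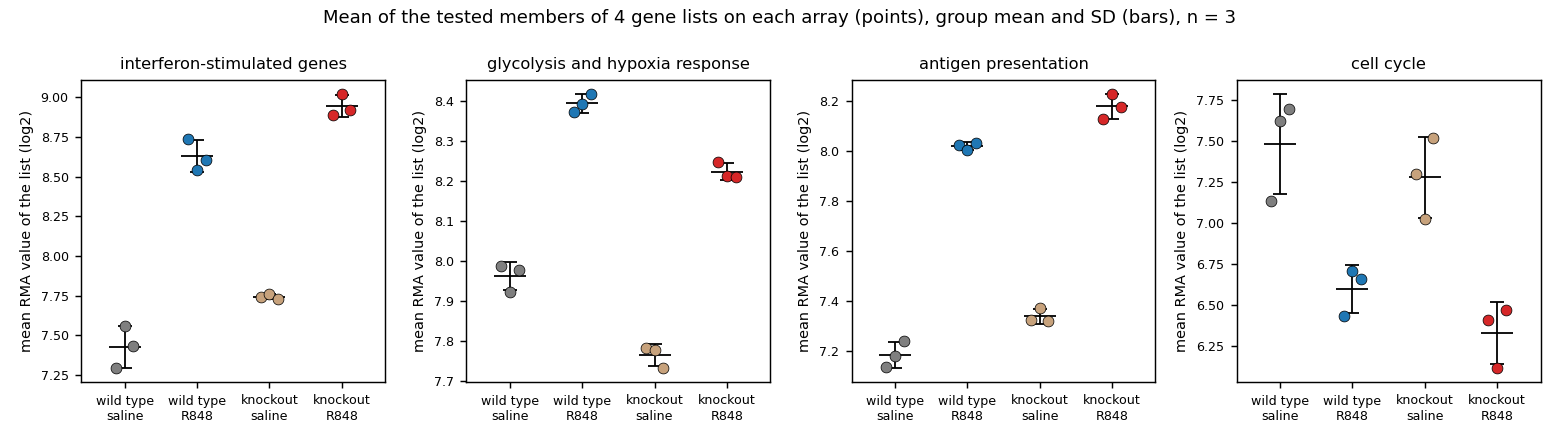
Mean RMA value (log2, vertical axes) of the tested members of 4 gene lists on each array (points), with the group mean and SD (bars, n = 3). The axes do not start at 0. In each treatment, all 3 knockout arrays lay above the wild-type arrays for interferon-stimulated and antigen presentation genes and below them for glycolysis genes, while the cell cycle values of the genotypes overlapped in both treatments.

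Averaged over treatments, 251 genes differed between genotypes, 109 higher and 142 lower in knockout cells, 8 of them at least 2-fold. Largest were Akr1e1 (2.77 ± 0.12, SE), Kcnma1 (1.94), Erdr1 (1.93), Mid1 (1.68) and the interferon-inducible gene Slfn4 (1.22), and lowest Ifi208 (-1.26), Cxcl1 (-1.24), Uck2 (-0.91), Dcstamp, a gene of osteoclast fusion (-0.90), and H2-Q10 (-0.75). Of the interferon-stimulated genes 17 of 32 were higher, and 28 adjusted over the list alone, led by Mx1 (0.69), Ifit1 (0.53), Cmpk2 (0.52) and Stat2 (0.51), and of the glycolysis genes 5 of 22 were lower, and 15 adjusted over the list alone, among them Pgk1 (-0.40), Slc2a1 (-0.38), Pfkl (-0.28) and Pkm (-0.27). Both lists held with an estimated correlation (adjusted p = 0.0298 and 0.00343), as did antigen presentation (0.0298), with 4 of 25 higher, H2-Ab1 (0.39), Cd83 (0.38), H2-Aa (0.36) and Tap1 (0.30), and 12 adjusted over the list alone. Dendritic cell markers, with a median of 0.13, held too (adjusted p = 0.0298 with an estimated correlation), with 0 of 9 past the threshold and 4 adjusted over the list alone. Camera with the preset correlation only called cholesterol synthesis (median -0.27), cell cycle (-0.23), NRF2 (-0.17, with Slc7a11, Gclm and Gclc lower) and protease and serpin genes (-0.10) lower. It called TLR receptors and adaptors (0.07), macrophage identity genes (0.08, with Fcgr4 higher) and cytokines (0.06, with Il18 higher) higher. Their adjusted p with an estimated correlation lay between 0.0627 and 0.508. The cholesterol synthesis difference leaned on knockout replicate 3, whose list mean was lowest with saline (6.90) and with R848 (7.26). That of cell cycle genes leaned on knockout replicate 2, lowest in both treatments (7.03 and 6.12). The count was 73, 104 and 150 without wild-type R848 replicate 2, 3 and 1, 85 and 162 without knockout saline replicate 2 and 1, 91 without knockout R848 replicate 2 and 125 without wild-type saline replicate 3. With arrays of 1 genotype and number fitted as correlated pairs, 118 of the 251 genes were past the threshold, with 14 of the interferon-stimulated, 4 of the glycolysis and 1 of the antigen presentation genes (H2-Aa), and without H2-Q10, H2-Ab1, Cd83, Tap1, Slc7a11 and Il18. The share of higher genes was 43.4%, 65.8% after median centring and 68.2% after cyclic loess.

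Genes near the targeted locus were compared with all others. Among the 50 tested genes on either side of Rasgef1b on chromosome 5, 6 of 100 were past the threshold in the averaged comparison (6%), against 243 of 13895 elsewhere (1.75%), an odds ratio of 3.59 (two-sided Fisher's exact test, p = 0.00886). They were Cxcl1, G3bp2, Gbp9, Hnrnpd, Hpse and Septin11, and without Cxcl1 the p was 0.0313 (Fisher's exact test). Gbp9 is of the same gene family as Gbp5 of the interferon list, and the window without Gbp9 was not tested. With arrays of 1 genotype and number as correlated pairs, 4 of 100 remained (Cxcl1, G3bp2, Gbp9 and Hpse), with an odds ratio of 5.08 (Fisher's exact p = 0.00983). With saline 2 of 100 were past the threshold, Hpse and Septin11 (Fisher's exact p = 0.0444), and with R848 1 of 100, Cxcl1 (Fisher's exact p = 0.127). In the averaged comparison with 20 genes on either side the odds ratio was 4.52 (Fisher's exact p = 0.0339), but with correlated pairs 1 of 40 genes, Hpse, was past the threshold there (Fisher's exact p = 0.286). With 100 genes on either side the odds ratio was 2.03 and no longer past the threshold (Fisher's exact p = 0.0936, and 0.17 without Cxcl1). Over whole chromosomes no share differed after adjustment, the smallest adjusted p being 0.28. Xist lay between 2.87 and 3.22 on all arrays, and the Y-linked genes Kdm5d, Eif2s3y and Uty between 5.51 and 7.87.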

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

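The tests of the explanations for Cxcl1, including the window around Rasgef1b with Cxcl1 left out, were chosen after the results were seen, as were the groupings that keep same-numbered arrays of a genotype together and the fit with correlated pairs. The counts over the other groupings of the arrays were chosen before. Cxcl1 stood out because its R848 response differed between the genotypes, with an interaction of -3.03. A weaker response of the knockout cultures as a whole is argued against by the 547 other genes raised at least 2-fold, whose interactions had a median of 0.04 (0.0433) with 90% of them, by the 5th and 95th percentiles, between -0.31 and 0.39. An allele of another mouse strain carried along with the targeted locus stays open and may contribute, since 5 of the other 99 genes in the window around Rasgef1b differed between genotypes (two-sided Fisher's exact p = 0.0313 without Cxcl1, and 0.0491 with arrays of 1 genotype and number as correlated pairs), although without Cxcl1 the window of 100 genes on either side gave p = 0.17, the windows of 20 and 100 with correlated pairs gave 0.286 and 0.228, and Cxcl1 was the only gene of the window past the threshold with R848. Gbp9, past the threshold in both fits, is of the same gene family as Gbp5 of the interferon list, which was higher in knockout cells. The window without Gbp9 was not tested. A sequence variant under the probes cannot be told apart from a change in RNA, because the saline difference of 0.28 was measured where wild-type Cxcl1 lay at 4.24, under the dim limit. Loss of Rasgef1b itself, the difference the design names, which the groups do not separate from the presence of Cre, also stays open and was not tested.

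Enpp4 also responded differently in the 2 genotypes by the test of the interaction, with 0.91 on the log2 scale. The Ras-ERK output genes had a median interaction of 0.23, a call of camera lost with an estimated correlation (adjusted p = 0.635). The genes raised and lowered by R848 had medians of 0.0267 and -0.04, past the threshold of camera against other genes. With an estimated correlation the first kept its call (p = 0.0475) and the second did not (p = 0.222), and neither passed against no change (fry p = 0.163 and 0.311). Rows that the platform table pairs with no gene symbol or with several are left out of the comparisons, and 5174 of them were tested apart. R848 gave 270 rows higher and 334 lower past the threshold in wild type, and 320 higher and 432 lower in knockout. Averaged over treatments, 18 rows were higher and 1 lower in knockout.

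For the genotype averaged over treatments, 1 of 100 drawn groupings of the arrays, the real one, gave as many as 251 genes, and the highest of the others gave 89. This argues against chance only if all 12 arrays are independent, and same-numbered knockout arrays had correlated residuals. If arrays of 1 genotype and number share a culture, which the labels do not say, there are 10 groupings, too few for a share under 0.05, with 251 genes for the real one and 89 for the highest other. For R848 averaged over genotypes chance is excluded, with 7039 genes in the real grouping (1 of 100) and 1 in the highest other. For the interaction, 5 of 100 gave 2 or more genes, the real one included. The highest of the others gave 251, the number for the averaged genotype difference, which points to a structure of the samples: exchanging the genotype labels in 1 treatment turns the averaged difference into an interaction. These groupings therefore give no chance rate for the count. For Cxcl1 chance is argued against by its own test (-3.03 ± 0.20, SE, limma adjusted p = 4.58e-06), whose call held without each of the 12 arrays in turn, while for Enpp4, whose call was lost without any of the 9 arrays outside the knockout saline group (adjusted p between 0.0545 and 0.122), it stays open. For the comparisons of 3 against 3 arrays there are 10 groupings, too few for a share under 0.05. In each, 1 grouping, the real one, gave as many genes: 5387 with a highest other of 0 for R848 in wild type, 5858 with 0 for R848 in knockout (whether or not a grouping parts all 3 same-numbered pairs), 47 with 5 for the genotypes with saline and 19 with 0 for the genotypes with R848.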

How the results depend on the processing

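All alternatives were chosen before the data were examined, except the gene lists under other scalings and the fit with correlated pairs. The cause of a change was not tested unless the alternative's construction shows it. Requiring a log2 change of at least 1 as well left 1014 (R848 in wild type), 1086 (R848 in knockout), 1043 (R848 averaged), 5 (genotypes with saline), 7 (genotypes with R848), 8 (genotypes averaged) and 1 gene (interaction, Cxcl1). The 47 genes with saline became 31 without a filter and 8 in a fit of 6 arrays, which has fewer arrays to estimate the spread. With 1 surrogate variable the genotype counts were 122 with saline, 30 with R848 and 505 averaged, and with array weights the averaged count was 393. The surrogate variable was the largest pattern in the residuals of the group fit, so it left the group differences unchanged. Removing that pattern lowers the residual spread, so the higher counts follow from its construction and are no sign of further genotype differences. Apart from knockout saline with knockout R848, no 2 groups met the criterion for pairing by number: over all groups 12 of 18 same-numbered pairs had residuals correlated over 0.1 (range -0.21 to 0.33), and 9 of 12 arrays correlated best with their own number, a hint from the data. With the replicate number as a block the counts were 99 with saline and 402 averaged, which included all 47 and all 251 genes, 21 with R848, 2 for the interaction, and 5676 and 6180 for R848 in wild type and knockout, where the block changed no call of a named gene or list in knockout. With arrays of 1 genotype and number as correlated pairs (estimated correlation 0.174), the averaged count of 251 became 118, all among the 251, since fewer independent units then carry the genotype, and Rasgef1b averaged kept its -0.68 but not its call (adjusted p = 0.054). The other counts were 50 with saline, 21 with R848 and 2 for the interaction. Rasgef1b averaged over treatments kept its -0.68 with an intensity trend and robust spread but not its call (limma adjusted p = 0.0643). The correlation of the R848 responses was 0.9563 without a filter and 0.9769 with a stricter one. The median interaction of genes raised by R848, 0.0267, was no longer past the threshold without a filter (p = 0.0637) or without wild-type saline replicate 3 (0.01, p = 0.0576), nor was the -0.04 of genes lowered by it with an estimated correlation (p = 0.222) or without wild-type saline replicate 1 (-0.0133, p = 0.14). The window of 100 genes on either side of Rasgef1b gave an odds ratio of 2.03. Lists past the threshold numbered 12, 10, 10, 10, 1 and 11 for R848 in wild type, R848 in knockout, genotype with saline, genotype with R848, interaction and genotype averaged. With an estimated correlation they were 5, 3, 1, 3, 0 and 4, with fry 20, 20, 4, 4, 0 and 6, and without a filter the interaction had 0. Markers of haematopoietic progenitors, whose median with R848 in knockout was 0.0133, turned direction under fry (adjusted p = 0.00999), a test that does not compare them with other genes. Leaving out 1 array gave 4717 to 5417 genes for R848 in wild type, 5266 to 5898 in knockout and 6643 to 6961 averaged, 10 to 65 for the genotypes with saline, 13 to 25 with R848 and 73 to 249 averaged, and 1 to 2 for the interaction. Rasgef1b then ranged from -0.865 to -0.445 with saline, -0.81 to -0.385 with R848 and -0.76 to -0.5475 averaged, the correlation from 0.9609 to 0.9668, and the median interactions from 0.01 to 0.0375 and from -0.0533 to -0.0133. Lists past the threshold ranged from 9 to 13, 9 to 11, 8 to 10, 8 to 12, 0 to 2 and 9 to 12, in the order above. Under median centring 159 list results kept direction and side of the threshold, 7 were no longer past it and 2 newly past it, and under cyclic loess these numbers were 163, 2 and 3. Of the values of named genes without 1 array, 7437 kept both, 310 were no longer past the threshold and 17 newly past it. Signal near background limits dim genes, of which 8101 were not tested.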

Other observations

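The tests of explanations in this part were chosen after the results were seen. So were gene lists for ribosome biogenesis and for the supply of nucleotides and amino acids, written because such genes were among those lower in knockout cells, so their counts are a description and not a test. Averaged over treatments, 38 of 38 tested genes for ribosome biogenesis and the nucleolus had a negative difference, with a median of -0.23, and 11 were past the threshold, or 8 with arrays of 1 genotype and number as correlated pairs. Among these 8 were the nucleolar protein gene Nop58 (-0.50), Dkc1 (-0.50) and Mdn1 (-0.34). Of 23 genes for the supply of nucleotides, polyamines and amino acids, 22 were negative and 7 past the threshold, or 3 with correlated pairs, Uck2 (-0.91), Adss (-0.51) and Mthfd1l (-0.39). After median centring and cyclic loess the medians of these lists stayed negative, at -0.20 and -0.19 for ribosome biogenesis and -0.21 and -0.19 for supply. The transcription factor gene Myc had a difference of -0.40 ± 0.09 (SE, limma adjusted p = 0.036, and 0.0717 with correlated pairs). R848 raised 21 of the 38 ribosome biogenesis genes in wild type and lowered 1.

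Interferon-stimulated genes had higher medians in knockout cells, a call of camera that with an estimated correlation held with R848 (adjusted p = 0.0481) but not with saline (0.0957), with 4 of 32 members past the threshold with saline and 0 with R848. Median centring and cyclic loess left the medians of the list at 0.33 or more. Both act on values that RMA had already brought to nearly the same distribution, so they cannot test the RMA step itself. A stimulus like R848 already present in the saline knockout cultures is argued against by 531 other R848-raised genes. Their saline genotype difference had a median of 0 and a 75th percentile of 0.10, below the 0.30 of the interferon list. Because these genes were picked by their response to R848, a stimulus that raises mainly interferon-stimulated genes cannot be told apart and was not tested. Dendritic cells or their precursors among the knockout cells may contribute and cannot be told apart, because their markers had medians of 0.16 with saline and 0.09 (0.0933) with R848, of few and mostly dim genes; the brightest, Cd209a, lay at 8.85, differed by 0.52 with saline and -0.03 with R848, and is also listed for alternative activation. Loss of Rasgef1b, which the groups do not separate from the presence of Cre, stays open and was not tested.

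Akr1e1, Erdr1, Kcnma1, Mid1 and Gdf3 were higher in knockout cells past the threshold both with saline and with R848, and wild-type Akr1e1 lay under the dim limit, at 4.03 and 4.10. A different mix of sexes is argued against by Xist and the Y-linked genes, whose largest genotype difference was 0.15, and alleles flanking Rasgef1b by the position of the genes, with 0 of the 5 within 100 tested genes of it and none on chromosome 5. Erdr1 and Mid1 both lie on the X chromosome, so they may not be separate differences. Whether the bright row of Kcnma1 reads its named gene or other RNA cannot be told apart, because the second row, which differed by 0.0217, lay under the dim limit, where differences are compressed. Strain differences elsewhere in the genome, the presence of Cre and loss of Rasgef1b stay open and were not tested.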
